A study of Gallus gallus with 40 samples.

How the data were processed

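The samples were caecal enterocytes of chickens taken 3 weeks after inoculation with Salmonella Enteritidis and of uninfected birds of the same families. Per the labels' protocols, cells were scraped from the caecal mucosa, dissociated with collagenase, and sorted on side scatter and native green fluorescence. Total RNA was amplified to cDNA and labelled with Alexa Fluor 555 or 647. An infected and a control bird of one family were hybridised together on a printed long-oligonucleotide array of chicken genes. The 40 arrays came from 2 lines, called N and 6 in the labels, with 10 sibling pairs per line and 2 arrays per pair with the dyes exchanged. The series title speaks of resistant and susceptible birds, and the labels used here do not say which line is which. Housing of the infected and control birds was not given in the sources used here.

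Per the file headers, the slides were read at 635 and 532 nm with local background and without ratio normalisation by the scanner program. The intensity values are pixel means and medians of each spot and of its surroundings, on a linear scale, as the scanner wrote them per the file headers. The percent values give the share of a spot's pixels brighter than background plus 2 SD, or saturated, per the file headers. The score used here is the spot flag of the scanner program, deposited unchanged, in which not-found spots carry a negative value. The deposited value table holds log2 ratios made by the authors; the submitters' processing notes name limma without a version, and background and normalisation methods were not given in the sources used here. Set against the scanner values, each deposited column followed log2 of red (635 nm) over green (532 nm), with Pearson r across probes of 0.709 to 0.992 (median 0.959). The columns were not centred on their medians. The direction of the ratios is settled from the files, but a correlation does not test their scale, and the method of normalisation stays unknown. All 40 value columns were used.

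The deposited log2 columns of line N from the first hybridisation campaign had medians of -0.02, 0.03, 0.03, 0.15, 0.04, 0.27, 0.09, 0.16, -0.43 and 0.26 for replicates 1 to 5 and 16 to 20. Those from the second campaign had medians of 0.18, 0.14, 0.28, 0.14, 0.11, 0.13, 0.22, 0.37, 0.94 and 0.27 in the same order. In line 6 the deposited medians were 0.04, 0.19, 0.08, 0.12, 0.07, 0.12, 0.10, 0.10, 0.95 and -0.78 in the first campaign. In the second campaign they were -0.04, 0.43, -0.00, -0.01, -0.00, 0.39, 0.24, 0.66, 0.13 and 0.52.

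Values were computed in R 4.3.3 with limma 3.58.1, and tables and plots in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Background was corrected with normexp (offset 50) over all spots, and each array was normalised with loess, control spots having no weight. The log2 ratio was turned to infected over control by the dyes in the labels, and the 2 dye-swapped arrays of a pair were averaged to 1 value, so that a pair is the replicate. Of 21168 spots per array, 708 were controls and left out of the tests. A probe counted as above background where over 50% of its pixels exceeded background plus 2 SD, and 9804 of 20460 probes reached this in at least 1 channel on at least 10 of the 40 arrays. Saturated spots were kept. No pair of arrays held identical values.

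Between 10.9% and 49.2% of probes per array were above background at 635 nm (median 25.5%) and between 13.7% and 54.8% at 532 nm (median 28.6%). Median spot brightness lay between 80 and 318 at 635 nm against local backgrounds of 66 to 307, and between 140 and 574 at 532 nm against 99 to 467. The number of arrays limits the precision of each value, and small ratios of dim probes are pulled towards 0 by the offset. The 2 arrays of a pair, turned the same way, correlated across kept probes with a median r of 0.885 (0.779 to 0.945).

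Gene names came from the array's own annotation and from a table of RefSeq genes. Of the 20460 probes, 10987 received a gene name (9373 symbols) and 9473 stayed unnamed. Current symbols matched for 8643 probes, older ones were updated for 413, the name in the file was kept for 955, and the others were reached through accessions, locus tags or descriptions. For a gene with several probes, the one with the highest mean brightness stood for the gene, and for genes reported as changed by infection over all genes tested the values of other tested probes are stated.

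All 20 pairs entered one limma model with a mean per line, so both lines shared one estimate of the spread (18 residual and 3.01 prior degrees of freedom). The contrasts were the mean of line N against 0, the mean of line 6 against 0, and line 6 minus line N, each with Benjamini-Hochberg adjustment over 9804 probes and a threshold of 0.05. A second model added a slope per line on the infected bird's caecal load. Adjusted p-values of single genes are from limma throughout. The design, the gene lists and the alternatives were fixed before the data were examined, except where stated.

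The 25 lists held cytokines and chemokines, antimicrobial and acute phase proteins, Th1, Th2, and regulatory T and Th17 genes, pattern recognition, interferon stimulated genes, antigen presentation, absorptive enterocyte genes, junctions, T and NK, B and plasma, and macrophage markers, goblet, endocrine and stem markers, stromal markers, erythrocyte genes, cell cycle, immediate early and heat shock genes, the unfolded protein response, oxidative phosphorylation, ribosomal proteins, cholesterol biosynthesis, fatty acid oxidation, xenobiotic defence and apoptosis. With at least 5 measured genes asked for, 24 were tested; the Th1 list had too few. Lists were tested with camera (preset correlation 0.01), adjusted over 72 tests, beside camera with an estimated correlation and fry, whose p-value asks whether the genes of a list move one way on balance. An exact sign-flip test of each list's mean per pair (1024 flips, two-sided, adjusted over both lines) was added after seeing the data. The T and NK list includes SAP30L, a corepressor subunit entered in error, and the ribosomal list includes the paralogues RPS27L and RPL22L1 by their names. Matching through synonyms brought SH2D6 into the B cell list and LSP1P1 into the macrophage list.

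Genes named in the text were chosen by rule. In each contrast these were the 12 largest rises and 12 largest falls among genes past the threshold with the same direction in at least 8 of 10 pairs. For the line difference, opposite signs or at least a 1.5-fold difference were required. Up to 4 members per list past the threshold over all probes or over the list alone were added, with the 3 brightest members of 6 immune lists. Where fewer than 10 genes passed, the 10 smallest p-values were named by value only. Probes named outside this rule are marked as chosen after their values were seen. Results of some genes are not reported here, though they are counted.

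Caecal load was compared between lines with a two-sided permutation test (100000 resamples), and weight gain within pairs with an exact two-sided sign-flip test (1024 flips). Alternatives covered background correction, normalisation, the filter on dim probes (stricter: both channels on 20 arrays), the deposited table, single campaigns, all 40 arrays, array weights, the variance prior, each line alone, weight as a covariate, 1 probe per gene and leaving out each pair. Median pixel values, hybridisation day and sire family as random blocks, and the removal of probes numbered near interferon probes were added after seeing the data. The dates in the labels form 14 hybridisation days, none of which held arrays of both lines. Line and session therefore cannot be told apart in the line difference, although each ratio was formed within an array. On simulated data of 9804 probes with 200 changed, 16.4% of changes of 1.41-fold, 80.6% of 2-fold and 98.5% of 4-fold were called in line N, and 20.9%, 71.6% and 98.5% in line 6, with 6 of 9604 unchanged probes called in each. A simulated slope of 1 on load in line N was recovered for 76.5% of 200 probes. The simulations drew probes independently and gave both lines the same spread. The median SD between pairs of the real data was 0.53 in line N and 0.63 in line 6, a difference that these rates do not cover.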

Results

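Expression was measured in sorted caecal enterocytes of 20 infected chickens and their 20 uninfected siblings, 10 pairs from line N and 10 from line 6, on 40 two-colour arrays. Values below are log2 ratios of infected over control birds, given as the mean over 10 pairs with the SD between pairs, unless an SE is named. Of 20460 probes, 9804 were bright enough to be tested. The median SD between pairs was 0.53 in line N and 0.63 in line 6.

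The first comparison asked how heavily the infected birds were colonised. Line 6 carried 7.70 ± 0.286 log CFU per g of caecum (SD, n = 10; 7.36 to 8.26) and line N carried 6.01 ± 1.15 (SD, n = 10; 3.68 to 7.51). The means of the lines differed by 1.69 log units (two-sided permutation test, p = 3.0e-05), and 1 line N bird reached the lowest line 6 value. The difference of medians was 1.25 (permutation p = 0.00072). Infected birds of line 6 gained 140 ± 22.9 g against 176 ± 33.9 g in their siblings, a difference of -35.1 ± 40.7 g (SD of the differences) with lower gain in 9 of 10 pairs (exact sign-flip test, p = 0.0254). In line N the gains were 167 ± 13.2 g and 174 ± 18.0 g, a difference of -7.0 ± 19.1 g with lower gain in 6 of 10 pairs (exact p = 0.309), and -2.22 g without replicate 20 (exact p = 0.617). The weight difference between the lines' responses, -28.1 g, did not pass a permutation test (p = 0.0637). Taken as a ratio, the line 6 gain differed by -0.308 on the log2 scale (exact p = 0.0527). Without replicates 4, 16, 17 or 20 the line 6 difference was -31.3, -32.2, -27.7 or -32.8 g, each with an exact p of 0.0508. Weight at inoculation differed by -1.2 g in line N (exact p = 0.611) and -7.3 g in line 6 (exact p = 0.123).

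**Figure D1:**
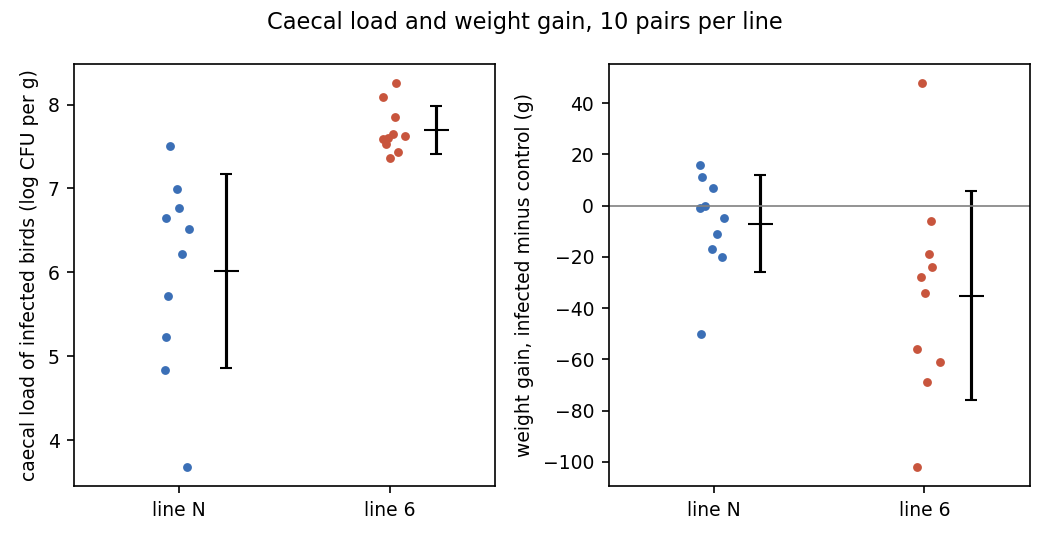
Caecal load of the infected birds (left, log CFU per g) and weight gain of the infected bird minus that of its control sibling (right, g) in lines N and 6; points are birds or pairs, bars the mean and SD. The line 6 loads lie between 7.36 and 8.26, and 9 of 10 line 6 pairs lie below 0 in weight gain.

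The second comparison asked which genes differed between infected birds of line N and their siblings. ATP12A, the catalytic subunit of the non-gastric hydrogen potassium ATPase of the colonic epithelium, fell 7.79-fold (log2 -2.96 ± 1.46 SD, n = 10, lower in 10 of 10 pairs, adjusted p = 1.06e-04). IFI6, an interferon-inducible gene, fell 3.21-fold (-1.68 ± 0.86, 10 of 10 pairs, adjusted p = 0.00801). RNF213, a large E3 ubiquitin ligase with antimicrobial activity, fell 2.65-fold (-1.41 ± 0.80, 10 of 10 pairs, adjusted p = 0.0120). LAMB3, a chain of the epithelial basement membrane laminin, fell 2.42-fold (-1.28 ± 0.68, 9 of 10 pairs, adjusted p = 0.0107). The ATP12A probe was above background on 15 of the 20 arrays for control birds and on 3 for infected birds, so its fold is open to understatement, and IFI6 was saturated on 17 control arrays, which understates its fold too. The other probes of RNF213 gave -0.87 (adjusted p = 0.232) and -0.40 (adjusted p = 0.477).

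The number of probes changed by infection in line N was 12 of 9804, 0 higher and 12 lower in infected birds, of which 5 changed over 2-fold. At an unadjusted p under 0.05 limma gave 815 probes, against 490.2 expected by chance. The count was 20, 19, 7 or 7 without replicate 2, 4, 16 or 18 of line N, and 5 of the 9 named genes (ATP12A, IFI6, RNF213, LAMB3 and FOSL2) passed in each of 20 fits that left out 1 pair. With line N fitted alone 4 of the 9 passed, and RNF213 (adjusted p = 0.0679) and FOSL2 (adjusted p = 0.117) were among those lost. Also lower were ENPP3 (-0.98 ± 0.63, 10 of 10 pairs), an ectonucleotide pyrophosphatase, and GPT2 (-0.91 ± 0.49, 9 of 10), the mitochondrial alanine aminotransferase. The others were FOSL2 (-0.70 ± 0.43, 10 of 10), an AP-1 subunit, and FABP7 (-0.51 ± 0.31, 9 of 10). Adjusted p-values of these 4 lay between 0.0107 and 0.0268. TRAM1L1 was measured at -0.56 (adjusted p = 0.0587). Chosen after their values were seen, 3 further probes had no gene name: RIGG07323 (-0.81), RIGG08750 (-0.90, above background on 1 infected and 9 control arrays) and RIGG15651, described as similar to HERC5. The last was not above background on any infected array and was at least 1.54-fold lower (adjusted p = 0.0173). RIGG07323 was numbered near the probe of IFIT5, an interferon stimulated gene, and whether it followed that probe was not tested. TGM4, also outside the rule, had a value of -3.66 ± 1.38 with all 10 pairs negative but an adjusted p of 0.0724 (0.00819 with line N fitted alone).

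Of 25 measured interferon stimulated genes in line N, 1 fell (IFI6) and 24 did not pass over all genes tested, while 8 fell when adjusted over the list alone. By value, USP18 stood at -1.21, MX1 at -1.09 and LY6E at -1.03, each negative in 10 of 10 pairs, with adjusted p-values of 0.183, 0.170 and 0.187. With line N fitted alone, LY6E passed over all probes (adjusted p = 0.0473). MX1 encodes an antiviral GTPase, and USP18 a protease that removes ISG15. A second LY6E probe gave -0.42 (adjusted p = 0.774). IRF8 stood at -0.53 (adjusted p = 0.624). The list had a mean of -0.60 ± 0.38 and was below 0 in 10 of 10 pairs (exact sign-flip test, adjusted p = 0.0234). It was lower by camera (adjusted p = 4.56e-11; adjusted p = 0.104 with an estimated correlation; fry adjusted p = 0.0239). In the same pairs the mean of the T and NK markers was 0.02 ± 0.28, that of the macrophage markers -0.00 ± 0.52 and that of the B and plasma markers 0.25 ± 0.40.

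Of 16 cholesterol biosynthesis genes in line N, 0 fell over all genes tested in limma (8 at an unadjusted p under 0.05) and 5 fell when adjusted over the list alone. MSMO1 stood at -1.47 ± 1.17 (10 of 10 pairs, adjusted p = 0.0724). CYP51A1 stood at -0.93 (adjusted p = 0.176), HMGCS1 at -0.87 (adjusted p = 0.187) and SCD at -0.84 (adjusted p = 0.264). The list mean was -0.41 ± 0.45, below 0 in 8 of 10 pairs (camera adjusted p = 5.69e-06; adjusted p = 0.179 with an estimated correlation; fry adjusted p = 0.0423; exact adjusted p = 0.0703). Of 30 ribosomal protein genes, 0 rose in limma over all genes tested and 0 when adjusted over the list alone (6 at an unadjusted p under 0.05), while 29 had positive values. Their mean of 0.27 ± 0.14 was above 0 in 10 of 10 pairs (camera adjusted p = 1.02e-07; adjusted p = 0.0422 with an estimated correlation; fry adjusted p = 0.0177; exact adjusted p = 0.0234). Swapping infected and control birds within pairs at random gave as many camera calls as the real 11 over both lines and their difference in 24 of 100 regroupings, so chance was not excluded for their number.

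Markers of other cell types were tested in the same pairs. The stromal list (12 genes) had a mean of 0.26 ± 0.22, above 0 in 9 of 10 pairs (camera adjusted p = 9.78e-04; adjusted p = 0.0940 with an estimated correlation; fry adjusted p = 0.0215; exact adjusted p = 0.0312). Of its members, 0 passed over all genes tested in limma (4 at an unadjusted p under 0.05) and 2 rose when adjusted over the list alone: SPARC at 1.08 (adjusted p = 0.164) and COL4A1 at 0.57 (adjusted p = 0.321). The B and plasma list (14 genes) was higher by camera (adjusted p = 0.00323), a call lost with an estimated correlation (adjusted p = 0.212). This list did not pass fry (adjusted p = 0.0958) or the exact sign-flip test (adjusted p = 0.232) either. Its mean was above 0 in 7 of 10 pairs, and 2 members passed when adjusted over the list alone, IGHM at 0.97 (adjusted p = 0.269) and EBF1 at 0.70 (adjusted p = 0.238). Xenobiotic defence genes (22) had a mean of 0.16 ± 0.28, positive in 7 of 10 pairs, and 0 members passed either threshold in limma (3 at an unadjusted p under 0.05). The list was higher by camera (adjusted p = 0.0230; adjusted p = 0.306 with an estimated correlation; fry adjusted p = 0.265). That call was lost without replicate 16 (adjusted p = 0.0727) or 19 (adjusted p = 0.166) of line N. It was also lost with plain background subtraction (adjusted p = 0.0541), median centring (mean 0.02, adjusted p = 0.0785), the stricter filter (adjusted p = 0.106) and array weights (adjusted p = 0.118).

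The remaining lists were not called in line N. Cytokines and chemokines (25 genes) had a median of -0.21 (camera adjusted p = 0.142), with CX3CL1 at -0.59 (adjusted p = 0.159) and MMP7 at -1.55 (adjusted p = 0.248) past the threshold when adjusted over the list alone. TNFSF10, LITAF and CCL4, the brightest members, stood at -0.34, -0.52 and -0.13. CCL4 was negative in 5 of 10 pairs, and its value leaned on replicate 19 (-1.506), the others lying between -0.245 and 0.262. Antimicrobial and acute phase genes (17) had a median of -0.05 (camera adjusted p = 0.169), with LYG2, a lysozyme, at -1.44 (adjusted p = 0.247) and the beta-defensin AvBD10 at -0.91 (adjusted p = 0.159) past the list-alone threshold. AvBD10 was above background on 0 infected and 8 control arrays, so its value lies near the floor of the assay and gives no firm fold. EXFABP, PIGR and TF stood at -0.65, -0.05 and 0.09, and a second TF probe gave -0.20 (adjusted p = 0.958). Among absorptive enterocyte genes (33), KRT19 at -1.85 (adjusted p = 0.0962) and EPS8 at -0.82 (adjusted p = 0.236) passed over the list alone only, and among junction genes (26) PARD6B at -0.60 (adjusted p = 0.193). Antigen presentation (16 genes, median -0.18, camera adjusted p = 0.266) included B2M at -0.46, BF1 at -0.31 and CD74 at 0.13, CD74 being saturated on 20 control and 17 infected arrays.

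**Figure D2:**
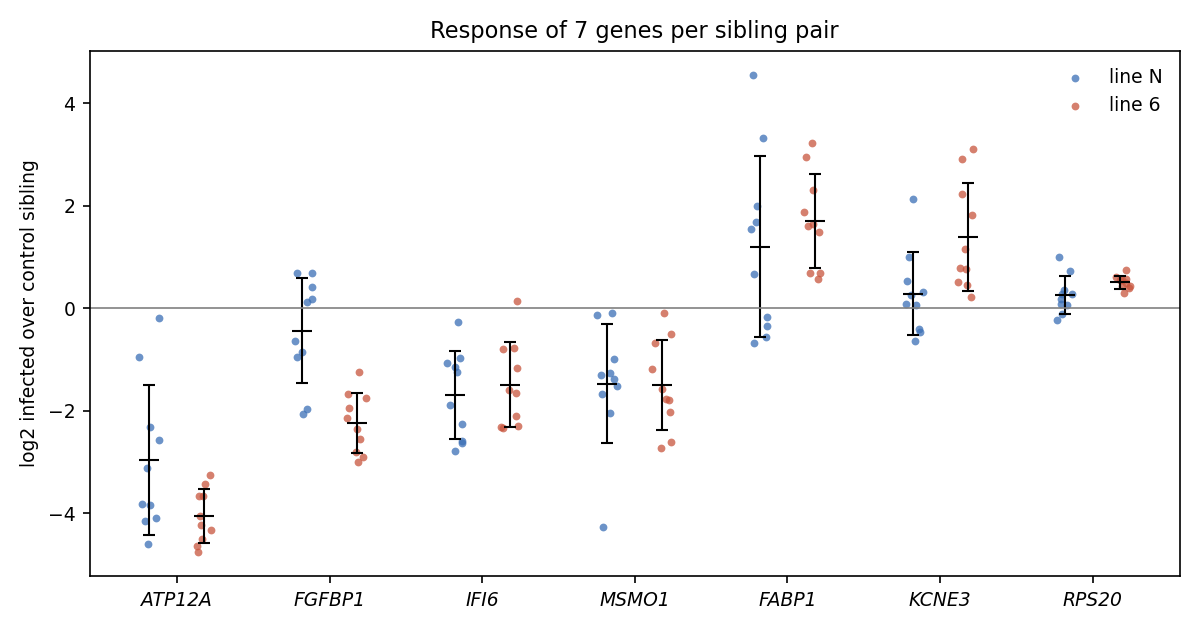
Log2 ratio of infected over control sibling for 7 genes in line N (blue) and line 6 (red); points are sibling pairs, bars the mean and SD over 10 pairs. ATP12A lies below 0 in each pair of both lines, and FGFBP1 in each pair of line 6.

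The third comparison asked the same of line 6. ATP12A fell 16.5-fold (-4.05 ± 0.52 SD, n = 10, 10 of 10 pairs, adjusted p = 1.47e-07). FGFBP1, a secreted carrier of fibroblast growth factors, fell 4.70-fold (-2.23 ± 0.59, 10 of 10 pairs, adjusted p = 3.84e-05). Among genes with a symbol, the largest rise was that of FABP1, the liver-type fatty acid binding protein of enterocytes, at 3.27-fold (1.71 ± 0.92, 10 of 10 pairs, adjusted p = 0.0423). POLR2H, a subunit shared by the RNA polymerases, rose 2.95-fold (1.56 ± 1.14, 10 of 10 pairs, adjusted p = 0.00622). ATP12A was above background on 18 control arrays and 1 infected array, so its fold is open to understatement.

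The number of probes changed by infection in line 6 was 148, 97 higher and 51 lower in infected birds, for 75 named genes, and 68 of the probes changed over 2-fold; 1332 had an unadjusted p under 0.05. The split of calls depended on the scaling, with 16 higher and 30 lower after median centring of the arrays and 58 higher and 60 lower in the deposited table. With line 6 fitted alone, 5 probes passed. Among them were ATP12A, FGFBP1 and, chosen after their values were seen, RIGG05835, described as transthyretin (-3.62 in the joint model), and RIGG04058, described as endothelin 2 (-0.68). Of the 31 named genes past the threshold in line 6, 3 kept their call in that fit. The count of 148 thus rests on the joint fit, in which line 6 (median SD 0.63) shared its spread with line N (0.53). Whether the shared spread or the larger joint fit raised the count was not tested. RIGG05835 was above background on 1 infected and 19 control arrays, so its fold is open to understatement. Without replicates 3, 16, 18, 19 or 20 of line 6 the count was 92, 70, 95, 76 or 70.

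Besides these, CLDN1, a tight junction claudin and the 1 member of 26 junction genes that fell, stood at -2.42 ± 2.10 (9 of 10 pairs), LGALS2, a galectin, at -1.73 ± 1.34 (9 of 10) and BCHE, butyrylcholinesterase, at -1.38 ± 0.72 (10 of 10). WLS, a carrier of Wnt ligands, fell by 1.41 (8 of 10 pairs) and FKBP1B by 1.11 (10 of 10). Adjusted p-values of these 5 lay between 0.00409 and 0.0444. MTNR1A (-1.04, adjusted p = 0.0104) and THUMPD3 (-1.15, adjusted p = 0.0270) passed too, but their probe numbers lay near those of interferon stimulated genes, in the same row of other blocks. They followed these with r = 0.709 and r = 0.949 across pairs, and a second THUMPD3 probe gave 0.48 (adjusted p = 0.673). MTNR1A was above background on 1 infected and 12 control arrays. Among the other large rises were KCNE3 (1.40 ± 1.05, 10 of 10 pairs), a potassium channel subunit of the intestinal crypt, BMP4 (1.27 ± 0.86, 9 of 10) and MSRB1 (1.23 ± 0.91, 9 of 10). The rest were METRNL (1.27 ± 1.32, 9 of 10), COX20 (1.14 ± 1.11, 8 of 10), ASF1A (1.13 ± 1.21, 9 of 10) and GPR128 (1.10 ± 0.65, 9 of 10). Adjusted p-values of these 7 lay between 0.0104 and 0.0459. A second BMP4 probe rose as well (1.05, adjusted p = 0.0250) and the third gave 0.52 (adjusted p = 0.30). RPL6 and ERP29 passed at 1.45 and 1.21, values of 1.01 and 0.87 without their most extreme pair, and a second ERP29 probe gave 0.20 (adjusted p = 0.746). Of 31 named genes past the threshold in line 6, 15 passed in each of 20 fits that left out 1 pair, while METRNL and WLS were lost in 15 of them, ASF1A and MCM4 in 13 and FABP1 in 11.

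Of 30 ribosomal protein genes in line 6, 7 rose over all genes tested and 0 fell, while 15 rose and 1, RPS27L, fell when adjusted over the list alone. Those that rose were RPL6, RPL22 (0.65), RPS13 (0.54), RPL30 (0.54) and RPS20 (0.51 ± 0.13, 10 of 10 pairs), with RPS6 (0.77) and RPLP0 (0.67), which like RPS27L were named after their values were seen. RPS20 was saturated on 12 infected and 5 control arrays, stood at 0.18 with print-tip loess (adjusted p = 0.679) and lost its call in 4 of 19 settings. RPL6, RPL22 and RPS13 also lost theirs in 4 of 19 settings each, and RPL30 in 5. Of 20 fits that left out 1 pair, RPL6 was lost in 4, RPL30 in 3, RPL22 in 2, RPS13 in 1 and RPS20 in 0. The list mean of 0.43 ± 0.24 was above 0 in 10 of 10 pairs (camera adjusted p = 6.30e-10; adjusted p = 0.0225 with an estimated correlation; fry adjusted p = 1.02e-04; exact adjusted p = 0.0234). Of 28 cell cycle genes, 3 rose, all of them subunits of the replicative MCM helicase: MCM2 at 1.33 ± 1.05 (8 of 10 pairs, adjusted p = 0.0250), MCM4 at 0.87 (adjusted p = 0.0423) and MCM5 at 0.69 (adjusted p = 0.0358). Of 20 fits that left out 1 pair, MCM2 was lost in 3, MCM4 in 13 and MCM5 in 6. MCM2 lost its call in 3 of 19 settings, MCM4 in 12 of 19 and MCM5 in 7 of 18. Adjusted over the list alone 5 rose, and TYMS was among them at 0.66 (adjusted p = 0.0514). The list was higher by camera (mean 0.34 ± 0.43, 7 of 10 pairs, adjusted p = 0.00118), a call lost with an estimated correlation (adjusted p = 0.418). It did not pass fry (adjusted p = 0.0706) or the exact sign-flip test (adjusted p = 0.162) either. In line N the same list had a mean of 0.15 (camera adjusted p = 0.0552).

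Of 25 interferon stimulated genes in line 6, 1 fell, IFI6 (-1.49 ± 0.83, 9 of 10 pairs, adjusted p = 0.00622, saturated on 18 control arrays), and 7 fell when adjusted over the list alone. By value, IFIT5 stood at -1.49 (adjusted p = 0.0611), IFIH1, a sensor of double-stranded RNA, at -1.10 (adjusted p = 0.107) and NMI at -0.81 (adjusted p = 0.0853), while IRF8 stood at 0.41 (adjusted p = 0.562). The list mean was -0.47 ± 0.59, below 0 in 9 of 10 pairs (camera adjusted p = 1.67e-08; adjusted p = 0.183 with an estimated correlation; fry adjusted p = 0.0706; exact adjusted p = 0.159). Beside it, the T and NK markers had a mean of 0.21 ± 0.19, above 0 in 9 of 10 pairs (exact adjusted p = 0.0312; camera adjusted p = 0.266). The B and plasma markers had a mean of 0.14 ± 0.13 (9 of 10 pairs, exact adjusted p = 0.0536) and the macrophage markers 0.20 ± 0.33 (6 of 10, exact adjusted p = 0.232).

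Of 16 cholesterol biosynthesis genes in line 6, 1 fell, MSMO1, the sterol C4-methyl oxidase (-1.50 ± 0.88, 10 of 10 pairs, adjusted p = 0.0174). It was saturated on 13 control and 2 infected arrays, so its fold is open to understatement. Adjusted over the list alone 4 fell, among them INSIG1 at -0.94 (adjusted p = 0.0950), HMGCS1 at -0.78 (adjusted p = 0.104) and LSS at -1.30 (adjusted p = 0.181). The list mean of -0.51 ± 0.29 was below 0 in 10 of 10 pairs (camera adjusted p = 2.05e-07; adjusted p = 0.104 with an estimated correlation; fry adjusted p = 0.0262; exact adjusted p = 0.0234).

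No other list was called by camera in line 6. FABP1 was the 1 member of 33 absorptive genes and of 29 fatty acid oxidation genes that rose. Adjusted over the list alone, CDX1 at 0.63 (adjusted p = 0.0665) and CA7 at 0.93 (adjusted p = 0.142) rose and KRT19 at -1.55 (adjusted p = 0.0686) fell. Of 24 immediate early and heat shock genes, HSPA8, a constitutive heat shock protein, rose (1.04 ± 0.94, 9 of 10 pairs, adjusted p = 0.0367). The HSPA8 call was lost in 6 of 20 fits that left out 1 pair and in 6 of 19 settings. Antigen presentation (camera adjusted p = 0.964) held CD74 at 0.74 (adjusted p = 0.0586), CTSB at -1.12 (adjusted p = 0.104) and PSMB1 at -0.59 (adjusted p = 0.105), all 3 past the threshold over the list alone; a second CTSB probe gave 0.05. CD74 was saturated on 15 infected and 11 control arrays. GSTA4 of the xenobiotic list (camera adjusted p = 0.142) stood at 0.90 (adjusted p = 0.0575). PIGR, which carries polymeric immunoglobulin across enterocytes, stood at 0.80 (adjusted p = 0.169). The cytokine list (camera adjusted p = 0.965) had a positive median of 0.06 and mean of 0.05 while camera's direction was down, and the antimicrobial list (camera adjusted p = 0.637) a median of -0.09 and a mean of 0.03. Among the brightest members, TNFSF10, CCL4 and LITAF stood at 0.52, 0.06 and -0.02, and EXFABP and TF at 0.71 and -0.09. BF1 and B2M of antigen presentation stood at -0.37 and -0.25. Adjusted p-values of these genes lay between 0.458 and 0.993. A second TF probe gave 0.65 (adjusted p = 0.452).

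**Figure D3:**
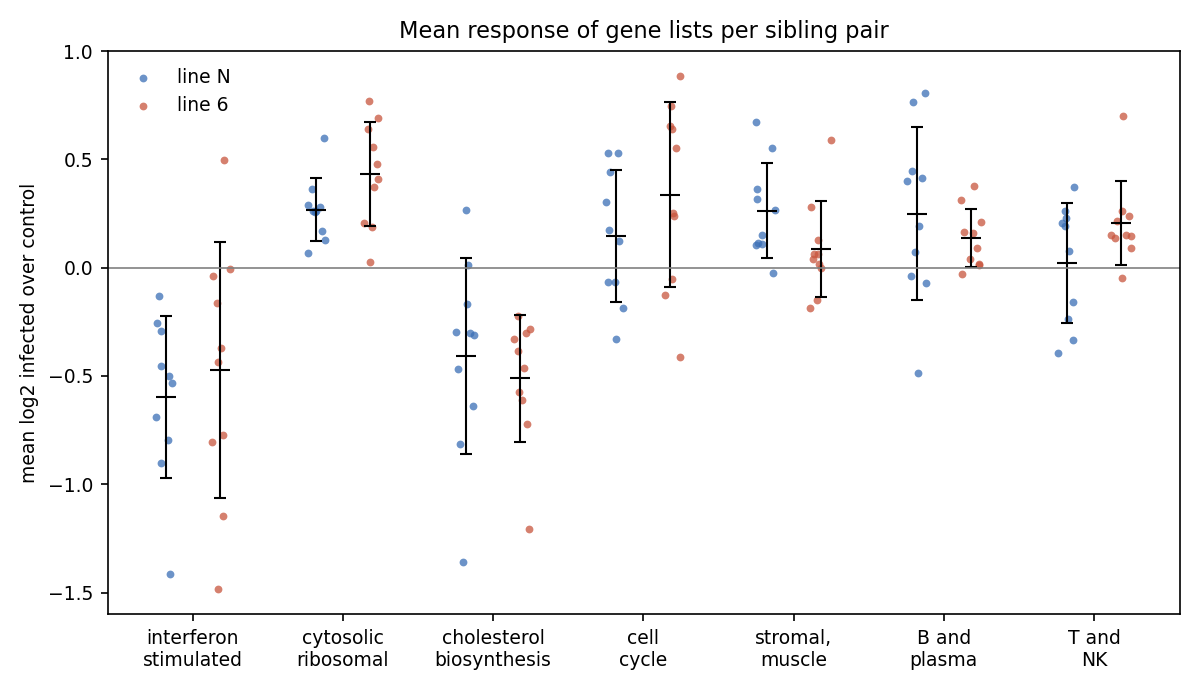
Mean log2 ratio of infected over control for the genes of 7 lists in line N (blue) and line 6 (red); points are sibling pairs, bars the mean and SD over 10 pairs. The ribosomal means lie above 0 in each pair of both lines, and the interferon means lie below 0 in 10 of 10 pairs of line N and 9 of 10 of line 6.

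The last comparison asked where the response itself differed between the lines. In limma 1 probe passed, and 752 had an unadjusted p under 0.05. The count was 0 without replicate 1, 2, 4, 16, 18, 19 or 20 of line N or 2, 3, 4, 16, 17, 18, 19 or 20 of line 6, and 2 without replicate 5 or 17 of line N or 1 of line 6. By value, FGFBP1 differed by -1.80 (adjusted p = 0.110), XRN2 by 0.82 (adjusted p = 0.110), and POLR2H by 1.72 (adjusted p = 0.241). HTF9C differed by 0.80 and KIAA0319L by 0.95 (adjusted p = 0.295 each). The values of MRPL2 (-1.30), FOSL2 (0.66), CYFIP1 (0.89) and NEGR1 (-0.90) had an adjusted p of 0.362 each, and that of PSMB1 was -0.87 (adjusted p = 0.40).

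ATP12A and IFI6 fell in both lines, 2 shared calls against 0.0624 expected from independent lists. Both lines shared one estimate of the spread per probe, so their lists are not independent and this expectation is no chance level. The responses of ATP12A and IFI6 did not pass the test of a difference (-1.09, adjusted p = 0.616, and 0.19, adjusted p = 0.926). ATP12A was near background on most infected arrays and IFI6 saturated on most control arrays. These differences therefore cannot show that the responses were alike. Across probes, which are not independent replicates, the line means correlated with r = 0.243 (rho = 0.175), and 55.4% had the same sign. The interferon, ribosomal and cholesterol lists did not pass the test of a difference between lines (camera adjusted p = 0.925, 0.197 and 0.585). The stromal list differed, with a mean of -0.18 in line 6 minus line N (camera adjusted p = 0.0316; adjusted p = 0.225 with an estimated correlation; fry adjusted p = 0.222). That call was lost without replicate 4 or 5 of line N (adjusted p = 0.0980 and 0.0865) and without replicate 3, 18 or 20 of line 6 (adjusted p = 0.0872, 0.0751 and 0.0593). It was also lost with plain background subtraction (adjusted p = 0.451), median centring (mean -0.05, adjusted p = 0.117) and the first campaign alone (adjusted p = 0.0772). All arrays of a given day came from 1 line, so the day and the line cannot be told apart in these differences.

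**Figure D4:**
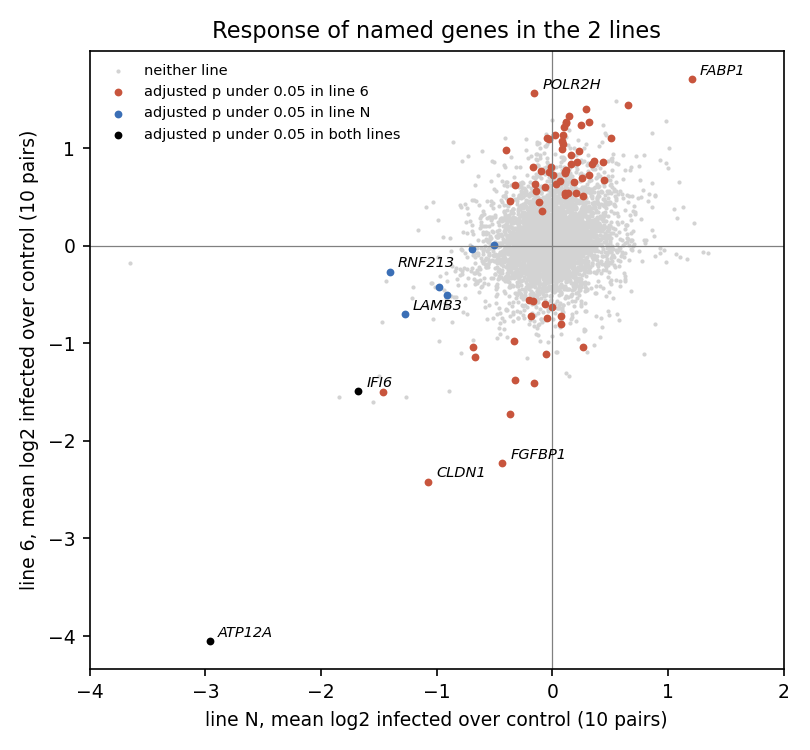
Mean log2 ratio of infected over control in line N (horizontal axis) and line 6 (vertical axis) for genes with a symbol that are reported here, 1 probe per gene, 10 pairs per line; colours mark genes with an adjusted p under 0.05 in line N, line 6 or both. ATP12A (-2.96 and -4.05) and IFI6 (-1.68 and -1.49) passed in both lines.

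Within lines, the response was set against the caecal load of the infected bird. In line N 0 probes passed in limma (801 with an unadjusted p under 0.05, smallest adjusted p = 0.134, for RNF20, SLC5A9 and KIAA0247). In line 6, where loads spanned less than 1 log unit, 8 probes passed, 3 with a positive and 5 with a negative slope, and 731 had an unadjusted p under 0.05. The smallest p-values were those of GEMIN5, an RNA-binding subunit of the SMN complex (7.39 ± 0.99 SE per log CFU, adjusted p = 0.00443), and GAS6, a ligand of the TAM receptor kinases (-4.16, adjusted p = 0.0178). TIMM22 (-3.36), SLC39A9 (4.24) and RCJMB04_17n19 (-3.45) passed as well, with 3 probes lacking a gene name. These genes were named after their values were seen. The line 6 count was 4, 4, 2, 36, 13 or 13 without replicate 1, 3, 5, 17, 18 or 20, and the line N count was 1 without replicate 1, 2, 3 or 19 and 6 without replicate 16.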

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

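The tests of a local surface defect, of extreme pairs taken per line, of leukocytes in either line and of housing, with the share of r over 0.6 between neighbouring probes and the exact sign-flip tests, were chosen only after the result was seen. The decision rules for extreme pairs, dividing cells and the relations with load were made stricter after a first run, which left those explanations open instead of decided, apart from extreme pairs in line N.

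Among 134 groups of 10 values, 7 held 1 pair far from the others by Dixon's test, against 6.7 that chance gives at about 1 in 20 groups. In line N these were CCL4 in replicate 19 (-1.506), IL13RA2 in replicate 3 (1.198), HSPD1 in replicate 5 (3.584) and MSMO1 in replicate 16 (-4.268). In line 6 they were RPL6 in replicate 20 (5.405), ERP29 in replicate 5 (4.299) and the cholesterol biosynthesis mean in replicate 3 (-1.209). The mean of the stromal markers (-0.178) differed between lines by camera with the preset correlation (adjusted p = 0.0316). It did not with an estimated correlation (camera adjusted p = 0.225) or by fry (adjusted p = 0.222). Outside the gene probes, 1.72% of negative control oligo spots were above background in either channel, against 0.356% of buffer spots, 0.0521% of empty positions and 33.4% of gene probes.

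Regrouping argued against chance for the number of probes changed in line N, where 1 of 100 regroupings, the real one, gave 12 calls and the highest other gave 2. The same held for the number in line 6, where 1 of 100 reached the real 148 and the highest other gave 28. Of the 99 other regroupings, 10 in line N and 33 in line 6 gave a call. The test therefore speaks to the counts and not to any single probe. For the line difference 1 of 100 reached the real 1 (highest other 0). The adjustment over all probes already makes any call rare, so a count of 1 probe cannot decide on chance here. That count was 0 in 15 of 20 fits that left out 1 pair. Chance was not excluded for the number of list shifts by camera: 24 of 100 regroupings gave as many as the real 11, and the highest other gave 23.

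THUMPD3, MTNR1A and 5 unnamed probes, called lower in line 6, carried probe numbers next to or near interferon probes and followed them across pairs with r of 0.683 to 0.949. Carry-over between neighbouring printing wells stayed open. Next-number pairs had a median r 0.0494 above that of pairs 1000 numbers apart (bootstrap 0.0257 to 0.0789). The rule set beforehand was a bound of 0.05 without an interval, and by it the value alone argued against carry-over. The bootstrap interval, which that rule did not name, holds the bound. Moreover, r was over 0.6 in 5.41% of 1053 next-number pairs against 0.336% of 892 distant ones. A local surface defect shared with the interferon probes was argued against, as 0 of the 7 probes lay in the block of the one they followed, but a defect shared by some of the 7 stayed open, as 4.55% of the probe pairs within the 2 groups, each with its interferon probe, lay close together in 1 block. Shared regulation of the named genes could be tested on 1 second probe alone, whose r with the interferon list mean was -0.198. Of the 7 probes, 2 had the number next to an interferon probe, so the next-number values speak to those alone, and without probes of such near numbers 136 probes passed in line 6.

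Interferon stimulated genes had means of -0.60 in line N and -0.47 in line 6. A few extreme pairs were argued against in line N (mean without the 3 lowest pairs -0.408, SE 0.0722). Fewer T and NK cells in the sorted cells of infected birds were argued against in line 6, where their marker mean was 0.205 (exact p = 0.00391, adjusted p = 0.0312). That list was the highest of 3, and camera did not call it (adjusted p = 0.266). Fewer B cells or macrophages stayed open in line 6, with marker means of 0.14 and 0.20 (exact adjusted p = 0.0536 and 0.232). Single markers there were TRBC -0.13, CD3E 0.29, XBP1 0.45, IGHM -0.04 and LGALS3 0.06. In line N fewer leukocytes stayed open, the cells having been sorted for enterocytes; the highest marker mean, that of B cells, was 0.25 (exact p = 0.0879; TRBC -0.08, CD3E 0.30, XBP1 0.45, LGALS3 0.08), and 0 of 14 T and NK, 2 of 14 B cell and 3 of 21 macrophage genes are in another list. A few extreme pairs stayed open in line 6 (mean without the 3 lowest pairs -0.183, SE 0.152), as did housing or another infection of the control birds, which would also give a mean below 0 in 2 lines. A response to infection may be the source and was not tested apart from these.

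Ribosomal protein genes were higher in infected birds of both lines, by 0.27 and 0.43 on average. Probe brightness was argued against, since the lower of the lines' percentiles among 10000 lists matched on brightness was 99.95, and so was dye or campaign, the lowest mean over lines, campaigns and dye orientations being 0.240. More dividing cells stayed open: the ribosomal mean followed the cell cycle mean over 20 pairs with r = 0.523 (permutation p = 0.0325), past the value of 0.5 set beforehand, but rho was 0.358 (permutation p = 0.153) and r was 0.429 without the 2 farthest pairs.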

How the results depend on the processing

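Median pixel values, day and sire blocks, removal of probes numbered near interferon probes and the exact list test were chosen after seeing the data; the other alternatives were fixed beforehand. Direction was compared for the named genes and the called lists only, and none past the threshold changed direction under the alternatives run. The cause of the shifts below was not tested unless the setting shows it. Counts that stayed within 1.5 times of those reported are not listed. The probes changed by infection in line N, 12 as reported, became 3 with plain background subtraction, 22 with median centring, 1 with the stricter filter on dim probes (3980 probes tested), 27 with all 40 arrays, 33 with array weights and 6 with a trended robust prior. The probes changed by infection in line 6, 148 as reported, became 87, 46, 355, 84 and 53 under plain subtraction, median centring, all 40 arrays, array weights and the trended robust prior. They became 71 without a filter, 92 in the first campaign alone, 79 with weight at inoculation as covariate, 57 with 1 probe per gene and 5 with each line fitted alone. In the fit of all 40 arrays the pair was a random block (correlation 0.865). The difference of 1 became 0 under plain subtraction, median centring, no filter, the stricter filter, the second campaign, the trended robust prior and the weight covariate, and 4 with all 40 arrays. With replicate numbers as a block across lines it became 0. Same-numbered pairs of the lines correlated with a median r of -0.00975 (-0.0930 to 0.0570), so the numbers do not pair the birds. Median centring moved the median of all probes in line N to -0.10 and that of the difference to 0.16. The 11 list shifts became 2 with an estimated correlation, both ribosomal, and 6 with fry. The weight gain of line 6 as a log2 ratio was -0.308.

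Leaving out 1 pair at a time gave 7 to 20 probes in line N, 70 to 195 in line 6, 0 to 2 for the difference (2 without replicate 5 or 17 of line N or 1 of line 6), and 10 to 13 list shifts. It gave 0 to 6 probes following load in line N and 2 to 36 in line 6, and a weight difference in line 6 of -44.3 to -27.7 g. Of the named genes' values, 33 lost their call with each line fitted alone, 21 each with plain subtraction and the trended robust prior, 16 with median centring, 15 with the weight covariate and 14 without a filter. Plain subtraction moved 7 of those that passed outward by 1.5 times or more: ATP12A to -4.60 in line N and -6.10 in line 6, GPT2 to -1.37, FABP7 to -0.94, BMP4 to 1.94, MTNR1A to -2.22 and MCM5 to 1.77. Leaving out pairs with discordant dye swaps gave no value, since 0 pairs had a negative correlation. Signal over background limited which probes could be tested: a median of 25.5% of probes per array exceeded background in the red channel and 28.6% in the green.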

Other observations

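The relations with load were chosen before the result was seen, and the rule for leaving them open was made stricter after a first run.

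Lists of other immune and metabolic genes were not called by camera in either line. Pattern recognition genes (22), the sensors of bacterial products and their signalling chain, had means of -0.12 in line N (adjusted p = 0.151) and 0.05 in line 6 (adjusted p = 0.961). In limma 0 members passed in either line, with 2 and 0 at an unadjusted p under 0.05. Regulatory T and Th17 genes (8) had means of -0.16 (adjusted p = 0.365) and -0.22 (adjusted p = 0.146). STAT3 at -0.65 and IKZF2 at -0.49 passed when adjusted over the list alone in line N (adjusted p over all genes 0.344 and 0.394). Th2 genes (6) had means of 0.07 in line N, against camera's direction (adjusted p = 0.988), and -0.04 in line 6 (adjusted p = 0.650). TIMD4 stood at 0.58 and 0.56, IL10RB at 0.30 and -0.46 and IL13RA2 at -0.06 and 0.04. The Th1 list had 4 measured genes and was not tested. IRF1 stood at -0.73 (adjusted p = 0.193) and -0.33, and IL18R1 at 0.04 and 0.02.

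Among metabolic and stress lists, fatty acid oxidation genes (29) had means of 0.10 (adjusted p = 0.142) and 0.15 (adjusted p = 0.585). In line 6 the list passed fry's test of change in either direction (adjusted mixed p = 7.95e-04). In limma 1 member, FABP1, passed there, and 7 were higher and 2 lower at an unadjusted p under 0.05. Antigen presentation and xenobiotic defence in line 6 and immediate early and heat shock genes in line N passed the mixed fry test narrowly (adjusted p = 0.0462 each). Oxidative phosphorylation genes (41) had means of 0.07 (adjusted p = 0.365) and -0.01 (adjusted p = 0.413), the second against a median of 0.00. Unfolded protein response genes (23) had means of -0.06 (adjusted p = 0.784) and 0.04, the latter against camera's direction (adjusted p = 0.834). Apoptosis genes (23) had means of -0.12 (adjusted p = 0.646) and 0.10 (adjusted p = 0.809). Immediate early and heat shock genes (24) had means of 0.13 (adjusted p = 0.151) and 0.26 (adjusted p = 0.112). In line N FOSL2 fell, and the chaperones SERPINH1 at 0.99 (adjusted p = 0.236) and HSPD1 at 0.82 (adjusted p = 0.269) passed over the list alone. The HSPD1 value leaned on replicate 5 (3.584), the next highest pair being 1.323. Absorptive genes had means of 0.15 in both lines (adjusted p = 0.356 and 0.783), and junction genes -0.14 (adjusted p = 0.215; fry mixed 0.0121) and -0.10 (adjusted p = 0.151). Goblet, endocrine and stem markers (17) had means of -0.02 in line N, against a median of 0.07 and camera's direction (adjusted p = 0.921), and 0.05 in line 6, against camera's direction (adjusted p = 0.955). Erythrocyte genes (5) had means of -0.08 (adjusted p = 0.798) and 0.08, the latter against a median of -0.09 (adjusted p = 0.955). In the line difference, the median, mean and camera direction also differed in sign for the absorptive, junction, goblet, erythrocyte, cholesterol, fatty acid and xenobiotic lists.

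The hypothesis that a list's shift grows with the caecal load of the infected bird was tested in 6 relations, over 10 pairs each. It stayed open in all, with a smallest adjusted p of 0.660 for r and 0.702 for rho. For interferon stimulated genes r was -0.426 (permutation p = 0.220) and rho -0.491 (permutation p = 0.156) in line N. In line 6 they were 0.458 (permutation p = 0.186) and 0.418 (permutation p = 0.234), and without the 2 farthest pairs r was -0.384 and 0.379 in the lines. For ribosomal proteins r was 0.338 (permutation p = 0.338) and rho 0.00606 (permutation p = 1) in line N. The line 6 values were -0.136 (permutation p = 0.708) and -0.115 (permutation p = 0.758), with r of -0.0724 and -0.249 without the 2 farthest. For cholesterol biosynthesis r was 0.00660 (permutation p = 0.986) and rho 0.164 (permutation p = 0.659) in line N. The line 6 values were 0.233 (permutation p = 0.514) and 0.248 (permutation p = 0.494), with r of 0.00740 and 0.103 without the 2 farthest.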
